A study of Mus musculus with 2 samples.

How the data were processed

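Gene expression was measured in mouse liver on 2 Agilent 2-colour arrays, 1 with RNA of wild-type mice and 1 with RNA of AID transgenic mice, all on a C57BL/6 background per the labels. On each array the Cy5 (red) channel held RNA of a liver treated with thioacetamide and the Cy3 (green) channel RNA of an untreated liver of the same genotype, per the labels. The ratio red over green is therefore treated over untreated. There was 1 array per genotype and no dye swap. Whether a channel held RNA of 1 animal or a pool, and the sex of the animals, are not given in the sources used here. Both arrays lay on the same slide and scan. Whether the animals were kept, and the RNA prepared and labelled, together is not given in the sources used here.

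The authors deposited the scanner output of each array. Spot mean signals and local background medians are intensity values as scanned, per the file headers. The processed signals are intensity values that the scanner software had background-subtracted, detrended and dye-normalized with a linear and a lowess step, per the file headers. The deposited log ratio is the log10 of red over green processed signal. It was exactly 0 on 7232 of 44397 spots of the wild-type array and on 8692 of the AID transgenic array, which include the spots whose green signal the software had replaced by a surrogate. The deposited error of each log ratio is a score from the scanner software's error model, in log10 units, and the deposited p-value per spot comes from the same model and describes 1 array, not mice. Feature Extraction is version 10.7.3.1 per the file headers and 10.5.1.1 per the submitters' processing notes. The deposited value table of the series equalled the scanner's log10 ratio on all 44397 features of each array, with a tolerance of 0, and its column medians were 0, so its scale, centring and direction are those of the scanner files.

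Values were computed in R 4.3.3 with limma 3.58.1. Mean signals were background-corrected with normexp and an offset of 50 against the background medians, then normalized by loess within each array, with weight 0 for control spots and outlier spots. Control spots were then left out, as were 197 non-control spots of the wild-type array and 207 of the AID transgenic array that the software marked as outliers. Aquantile normalization between the arrays was used for the comparisons of 1 channel across arrays and for levels. Spots of 1 probe were averaged, and the value of a gene is the mean over its probes. Further steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

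Of 39429 probes, 26055 were named by RefSeq accession through a symbol table of the mouse assembly GRCm38.p6, 3195 by symbol and 930 by a unique synonym, and 9249 had no match. This gave 22803 genes, 16730 of them with 1 probe and 6073 with more. No coordinates are printed, since the array design is not tied to that assembly.

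There were 5 comparisons: treated over untreated in each genotype, the difference between these 2 log2 ratios (AID transgenic minus wild-type), and AID transgenic over wild-type in the untreated and in the treated livers. No statistical test was possible with 1 array per genotype, so genes were described by a fixed rule of size. A gene was counted when its log2 value was at least 1 in size, which is 2-fold, and a probe of it was well above background in at least 1 of the channel values that entered. Where the dimmer side was not well above background, the fold is written as at least N-fold, computed on normalized log2 levels against the higher of the dim level itself and the lowest level well above background in that channel. Such bounds compare channels and are open to dye bias.

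The 40 gene lists, the rule for named genes and the alternative settings were fixed before the data were examined. For each list the number of measured members at 2-fold was counted, and its median log2 value was placed among 10000 random lists of the same size matched on mean log intensity in 20 bins. A list is said to stand apart when this percentile was at most 0.5 or at least 99.5. Percentiles describe these arrays only and carry no p-value. Named genes are the 10 highest and 10 lowest of each treatment ratio and of their difference, and the 5 highest and 5 lowest of each genotype comparison. They had to be well above background in every channel value that entered, with all probes on the same side of 0 and a gene symbol as name. Added to them were 2 to 4 leading members of each list described, members at 2-fold the other way, and a fixed set of liver and sex-linked genes, always named. Some of these genes are not reported here.

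The value after ± is the scanner software's error of its own log2 ratio, a technical error of the spot. The ratio printed before it comes from normexp and loess, so the error was not computed for that ratio. Across 399 probes with 10 spots each, the SD of the log2 ratio between spots had a median of 0.07 on either array. The median SD between probes of a gene was 0.14 on either array, and the median scanner error was 0.21. Spike-in controls had a slope of observed on expected log ratio of 0.939 on the wild-type and 0.938 on the AID transgenic array.

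The calls were tested on simulated data before use. In the wild-type comparison, run on 21669 probes, 85 of 100 probes simulated with a log2 ratio of 1.5 and 100 of 100 with 2.5 were counted, and 0 of 21469 unchanged probes. The median fitted sizes were 1.335 and 2.142, so the processing shrank the simulated ratios. The simulation held a dye trend, background and small spot noise, but no variation between animals. It scored only probes well above background in both channels, so it gives no rate of false calls for these arrays. In the AID transgenic comparison, run on 16691 genes, 1 of 100 random lists with no shift and 99 of 100 with a shift of 0.3 stood apart. These lists were drawn from the same genes as the reference lists, so the low rate without shift was set by the percentile limits. It gives no rate of false calls for lists whose genes vary together.

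The alternatives were no background correction, a normexp offset of 0, median centring in place of loess, the scanner's own processed signals, the deposited value table, stricter or no filters on dim probes, the brightest probe of each gene, single probes, a 3-fold threshold, the scanner's p under 0.01, other normalizations between arrays, and lists without shared members. Leaving out the genes of the 4 sex lists and of chromosomes X and Y was added after seeing the data.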

Results

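Liver RNA of C57BL/6 mice was profiled on 2 arrays, 1 for wild-type mice and 1 for mice with a transgene for AID. AID is activation-induced cytidine deaminase, the enzyme that deaminates cytosines in the antibody genes of B cells. Each array compared a liver after 6 months of thioacetamide in the drinking water (Cy5) with an untreated liver of the same genotype (Cy3). Thioacetamide is a hepatotoxin that liver enzymes activate and that is used to produce liver fibrosis in rodents. The comparisons ask how the liver transcriptome differs after this exposure in each genotype, and whether the genotypes differ. Of 43020 non-control spots, 56% on the wild-type and 53.9% on the AID transgenic array were well above background in Cy3, and 68.4% and 68.8% in Cy5. With 1 array per genotype, no difference given here has a replicate check, no p-value is given, and the number of arrays limits the precision.

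Transcripts tied to sex differed between the channels of the wild-type array. Xist, the RNA that coats the inactive X chromosome of females, was at least 6.18-fold higher in the treated than in the untreated wild-type liver, where it was not well above background. Its 2 probes differed in size, with an SD of 1.08, and both were higher. The Y-linked RNA helicase gene Ddx3y was at least 17.6-fold lower in the treated wild-type liver, and the Y-linked translation factor gene Eif2s3y at least 32.1-fold lower. On the AID transgenic array, Xist was not well above background in either channel, and Ddx3y had a log2 ratio of -0.11 ± 0.20. The sex of the animals is not given in the sources used here, so the wild-type treatment ratio and every comparison that holds the treated wild-type liver carry this difference.

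**Figure D1:**
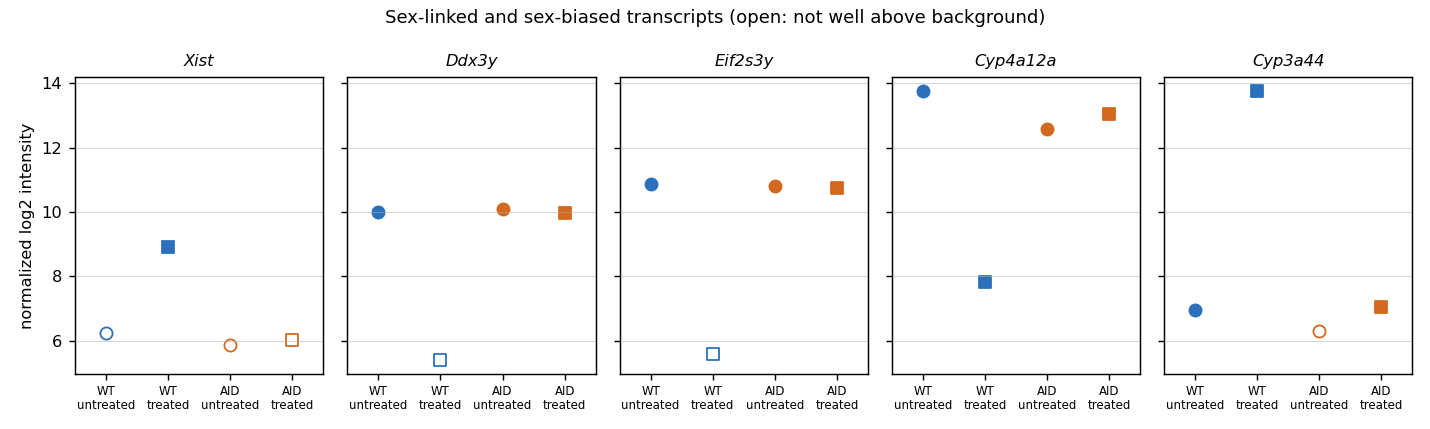
Normalized log2 intensity (vertical axis) of 5 transcripts in the 4 channel values (horizontal axis), circles for untreated and squares for treated livers, blue for wild-type (WT) and orange for AID transgenic (AID), open where not well above background. Xist was well above background in the treated wild-type liver at 8.90, where Ddx3y, Eif2s3y and Cyp4a12a had their lowest levels, at 5.39, 5.59 and 7.83.

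In wild-type mice, the treated liver had higher levels of NRF2 target genes, p53 target genes and cell cycle genes than the untreated liver. Of 31 measured targets of NRF2, a transcription factor for antioxidant and detoxification genes, 13 were at least 2-fold higher and 1 was lower, with a list median of 0.87 (percentile 100). The glutathione transferase genes Gsta1 and Gsta2 had log2 ratios of 4.32 ± 0.46 and 3.28 ± 0.37, and the carbonyl reductase gene Cbr3 had 3.02 ± 0.38. The member that was lower, Gstp1, had -1.79 ± 0.26 and is also on the list of male-biased liver genes. Among 24 targets of the tumour suppressor p53, 11 were higher and 0 lower (median 0.89, percentile 100), led by Phlda3 at 3.65 ± 0.42, the death receptor gene Tnfrsf10b at 2.32 ± 0.38 and the nuclease gene Aen at 1.95 ± 0.28. Cdkn1a, the cell cycle inhibitor p21, had 1.67 ± 0.46, but its 2 probes disagreed, with an SD of 2.44. Of 36 cell cycle genes 8 were higher (median 0.54, percentile 100), among them Ccnd1 at 2.78 ± 0.34, Cdc20 at 2.27 ± 0.36 and the proliferation marker Mki67 at 1.83 ± 0.32.

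Markers of fetal liver and liver tumours, ductular cells and matrix were also higher in the treated wild-type liver. Of 25 fetal liver and tumour markers 8 were higher and 1 lower (median 0.28, percentile 99.95). The desaturase gene Scd2 had 3.52 ± 0.44, Ly6d 3.28 ± 0.43 and Akr1c18 3.15 ± 0.41, while Tff3 had -1.04 ± 0.32. Afp, the fetal albumin-like protein alpha-fetoprotein, had 2.46 with an SD of 0.13 over 9 spots. Of 22 cholangiocyte and ductular markers 5 were higher (median 0.46, percentile 100), with Bicc1 at 1.35 ± 0.25, Krt23 at 1.27 ± 0.24 and Prom1, a member of the female-biased list whose 2 probes disagreed with an SD of 1.86, at 2.30 ± 0.49. Krt19, a bile duct keratin, had 0.59 ± 0.24. Among 29 fibrillar collagen and matrix genes 4 were higher and 1 lower (median 0.24, percentile 99.81). The collagen genes Col1a1 and Col3a1 had 1.60 ± 0.26 and 1.39 ± 0.24, and Col5a3 had -1.09 ± 0.23. None of 17 matrix remodelling enzyme genes reached 2-fold, but the list stood apart with a median of 0.31 (percentile 99.87), led by the gelatinase gene Mmp2 at 0.78 ± 0.25. Of 22 stellate cell and myofibroblast markers 1 was lower, and the list did not stand apart (median -0.01, percentile 26.5). Acta2, the smooth muscle actin of myofibroblasts, had -0.32 ± 0.21.

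Some groups of hepatocyte genes were lower in the treated wild-type liver, with median signs that turned with median centring. Of 33 genes of gluconeogenesis and amino acid catabolism 5 were lower and 0 higher (median -0.60, percentile 0.0, with median centring 0.15), led by the serine dehydratase gene Sds at -1.49 ± 0.24, Prodh at -1.38 ± 0.24 and Pck1, the gene of a rate-limiting gluconeogenic enzyme, at -1.34 ± 0.24. Of 26 periportal hepatocyte genes 4 were lower (median -0.37, percentile 0.06, with median centring 0.26, and not apart without shared members, percentile 1.46), and Aldh1b1 and Apoa4 were higher at 1.41 ± 0.24 and 1.24 ± 0.24. The urea cycle gene Cps1 had -0.96 ± 0.22. The 27 pericentral genes did not stand apart (median -0.18, percentile 1.41), although 4 were lower and 1, Aldh3a2, higher. The glutamine synthetase gene Glul had -2.47 ± 0.30 and Oat -2.36 ± 0.30, and Cyp2e1, which encodes a thioacetamide-metabolizing enzyme, had -0.92 ± 0.22. Of 22 genes of bile acid synthesis and transport 3 were lower (median -0.31, percentile 0.08), led by Slco1a1 at -4.12 ± 0.49 and Cyp7b1 at -4.02 ± 0.43, both male-biased genes. The bile acid list no longer stood apart without its sex-biased members (percentile 0.65), and with median centring its median of 0.37 lay 0.02 above that of all genes. Of 29 acute phase genes 9 were lower (median -0.38, percentile 0.01, with median centring 0.22), led by the serum amyloid genes Saa2 at -2.48 ± 0.31 and Saa4 at -2.43 ± 0.30, while the hepcidin genes Hamp2 and Hamp were higher at 3.42 ± 0.39 and 1.15 ± 0.23.

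Sex-biased liver genes had the largest wild-type ratios. Of 26 male-biased genes 22 were lower (median -1.89, percentile 0.0), and of 31 female-biased genes 22 were higher (median 1.71, percentile 100). The lowest 10 named genes were Cyp4a12a at -5.93 ± 0.63, Susd4 at -4.65, Cyp4a12b at -4.45, Elovl3 at -4.27, Slco1a1, Cyp7b1, Cabyr at -3.91, Serpina4-ps1 at -3.71, Cyp2d9 at -3.46 and Hsd3b5 at -3.34. All but Cabyr are on the male-biased list. Of the highest named genes, Cyp3a44 at 6.82 ± 0.85, Cyp2b13 at 5.05, A1bg at 4.46 and Cyp3a41b at 3.61 are on the female-biased list. Others were Cyp4a14 at 4.38, Gsta1, Phlda3, Scd2 and the carbonic anhydrase gene Car2 at 3.51. In all, 310 of 16662 measured genes were at least 2-fold higher and 274 lower, and 277 and 244 without sex-list, X-linked and Y-linked genes. The share of calls that were higher was 53.1%, and it was 65.8% with a normexp offset of 0 (782 higher and 406 lower), 72.5% with the scanner's processed signals (1584 and 602) and 94.4% with median centring (1730 and 102).

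In AID transgenic mice, the treated liver also had higher levels of NRF2 targets, p53 targets and fetal liver markers than the untreated liver. Of 31 NRF2 targets 15 were higher and 0 lower (median 0.95, percentile 100), led by Gsta1 at 4.41 ± 0.47, Cbr3 at 3.98 ± 0.46, Gsta2 at 2.95 ± 0.34 and Osgin1 at 2.45 ± 0.31. The quinone reductase gene Nqo1 had 1.17 ± 0.25, against 2.21 ± 0.35 in wild-type. Of 24 p53 targets 9 were higher (median 0.65, percentile 100), with Phlda3 at 2.42 ± 0.33, Aen at 1.61 ± 0.26 and Cdkn1a at 1.47 ± 0.52, where the 2 probes had an SD of 1.77. Of 26 fetal liver and tumour markers 8 were higher (median 0.50, percentile 100). Ly6d had 3.20 ± 0.42 and Afp 2.38 with an SD of 0.11 over 10 spots, and the proteoglycan gene Gpc3 was at least 5.05-fold higher. Of 35 cell cycle genes 1, Cdc20 at 1.35 ± 0.28, reached 2-fold, and the list stood apart (median 0.39, percentile 100). Mki67 had 0.82 ± 0.25.

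Macrophage, antigen presentation and interferon genes were higher in the treated AID transgenic liver. Of 35 macrophage and Kupffer cell markers 7 were higher (median 0.66, percentile 100), led by Cd5l at 1.48 ± 0.25, the cathepsin gene Ctss at 1.46 ± 0.25 and the adaptor gene Tyrobp at 1.16 ± 0.23. Of 9 MHC class II genes, which present peptides to helper T cells, 4 were higher (median 0.75, percentile 100), with H2-DMb1 at 1.503 ± 0.25, H2-Ab1 at 1.42 ± 0.24 and Cd74 at 1.23 ± 0.24. Of 38 interferon response genes 5 were higher (median 0.60, percentile 100), with Cxcl10 at 2.70 ± 0.34, Igtp at 1.66 ± 0.26 and Gbp3 at 1.64 ± 0.27. Of 34 inflammatory mediators 6 were higher and 1 lower (median 0.23, percentile 99.97, but 99.27 with median centring). The cytokine gene Il1b had 2.30 ± 0.37 and the chemokine genes Ccl5 and Ccl21a 1.70 ± 0.27 and -2.15 ± 0.30. On the wild-type array the macrophage (median 0.19, percentile 99.46), MHC class II (0.06, 63.0) and interferon lists (0.15, 96.1) did not stand apart. Cxcl10 was higher there too, at 2.305 ± 0.32, and its 2 ratios differed by 0.39 ± 0.47.

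Stellate cell markers and some groups of hepatocyte genes were lower in the treated AID transgenic liver. Of 23 stellate cell and myofibroblast markers 5 were lower (median -0.40, percentile 0.0), led by the contractile genes Cnn1 at -1.96 ± 0.36, Acta2 at -1.89 ± 0.29 and Myl9 at -1.63 ± 0.26. None of 28 collagen and matrix genes reached 2-fold, and the list stood apart below the random lists (median -0.23, percentile 0.0, with median centring 0.14), with Col1a1 at -0.44 ± 0.21. The ductular list did not stand apart (median -0.10, percentile 3.48), and Krt19 had -0.86 ± 0.28. Of 33 genes of gluconeogenesis and amino acid catabolism 9 were lower (median -0.60, percentile 0.0, with median centring 0.12), led by Got1 at -1.87 ± 0.27, Pck1 at -1.54 ± 0.26 and Hpd at -1.41 ± 0.24. Of 27 pericentral genes 9 were lower (median -0.32, percentile 0.0, with median centring 0.16), among them Oat at -2.54 ± 0.31, Glul at -2.52 ± 0.31, Cyp2c37 at -2.23 ± 0.29 and Cyp2e1 at -1.84 ± 0.28, while Tbx3 and Rnf43 were higher at 1.35 ± 0.24 and 1.30 ± 0.24. Without members shared with other lists the pericentral list no longer stood apart (percentile 2.17). Of 26 periportal genes 7 were lower (median -0.35, percentile 0.0, with median centring 0.36 and 0.02 above all genes), Cps1 had -0.99 ± 0.22, and Aldh1b1 and Apoa4 were higher at 1.06 ± 0.23 and 1.03 ± 0.23. Of 22 bile acid genes 3 were lower (median -0.44, percentile 0.0, with median centring 0.28), led by Slco1a1 at -1.91 ± 0.28 and Slco1a4 at -1.20 ± 0.26.

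Sex-biased genes had smaller ratios on this array, whose channels both held the Y-linked transcripts. Of 26 male-biased genes 5 were lower (median -0.64, percentile 0.0, with median centring 0.10), led by Susd4 at -3.97 ± 0.45 and the elongase gene Elovl3 at -1.99 ± 0.28. Of 27 female-biased genes 3 were higher, with Cyp2a4 at 2.41 the highest, and 2, Cyp2c39 at -2.27 and Cyp2c38 at -1.63, were lower (median 0.24, percentile 100). That list lay 0.04 below all genes with median centring, and it stood apart neither then (percentile 95.2) nor with every channel well above background (94.86). The highest 10 named genes were Gsta1, Cbr3, Ly6d, Car2 at 3.12, Gsta2, Cxcl10, Cyp2a21-ps at 2.68, Nr4a1 at 2.56, Saa2 at 2.504 and Osgin1. The lowest were Susd4, the retinoic acid hydroxylase gene Cyp26b1 at -3.23 ± 0.39, Zbtb16 at -2.64, Oat, Glul, Lpin1 at -2.44 (SD of 1.25 between its 2 probes), Cyp2c29 at -2.44, Sult2a8 at -2.37, Cyp2c39 and Cyp2c37. In all, 203 of 16691 measured genes were at least 2-fold higher and 158 lower, and 195 and 147 without sex-list, X-linked and Y-linked genes. Calls were higher in 56.2%, and in 69.7% with a normexp offset of 0 (620 higher and 269 lower), 76.6% with the scanner's processed signals (1528 and 466) and 96.2% with median centring (1358 and 53). With median centring the median log2 ratio of all measured genes, 0.03 on both arrays with loess, was 0.35 on the wild-type and 0.34 on the AID transgenic array.

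The 2 treatment profiles resembled each other across genes. Over 16249 genes measured on both arrays the log2 ratios had a Pearson correlation of 0.620 and a Spearman correlation of 0.634 across genes, which are not independent replicates. At 2-fold, 102 genes were higher on both arrays, against 3.80 for independent lists, and 69 were lower on both, against 2.62. Shared genes included Gsta1, Cbr3, Ly6d, Car2, Phlda3 and Scd2 among the higher and Susd4, Glul, Oat and Lpin1 among the lower. Opposite directions at 2-fold were seen for 2 genes higher in wild-type and 4 lower. Without sex-list, X-linked and Y-linked genes the Pearson correlation was 0.640, and 98 and 62 genes were shared.

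**Figure D2:**
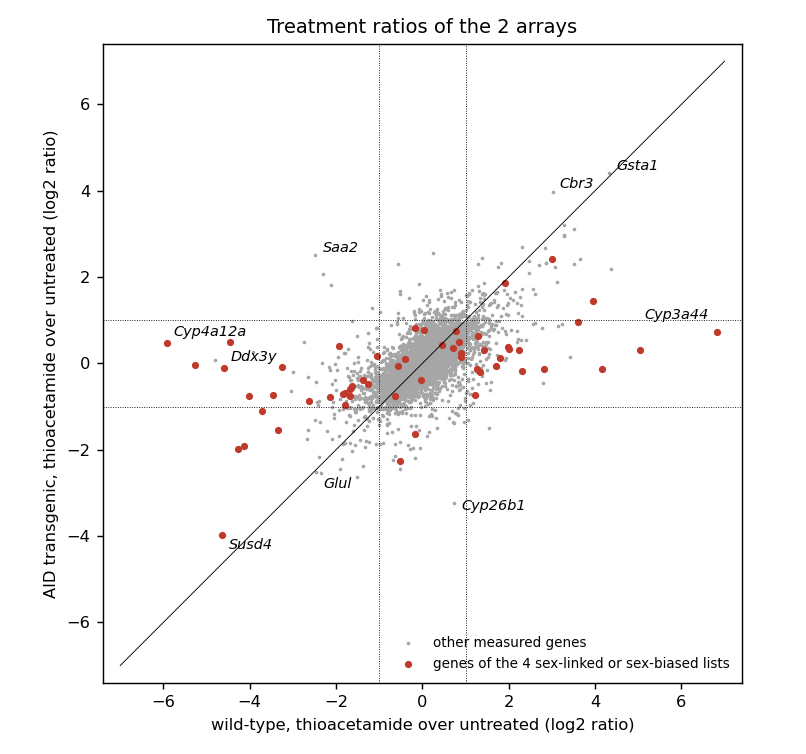
Log2 ratio of treated over untreated liver on the wild-type array (horizontal axis) and the AID transgenic array (vertical axis) for 16249 genes, with genes of the 4 sex-linked or sex-biased lists in red, dotted lines at 2-fold and the line of equal ratios. Gsta1 and Glul lie near the line, with 4.32 and 4.41 and with -2.47 and -2.52, while Cyp4a12a (-5.93 and 0.46) and Cyp3a44 (6.82, and at least 1.66-fold higher) lie far from it.

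**Figure D3:**
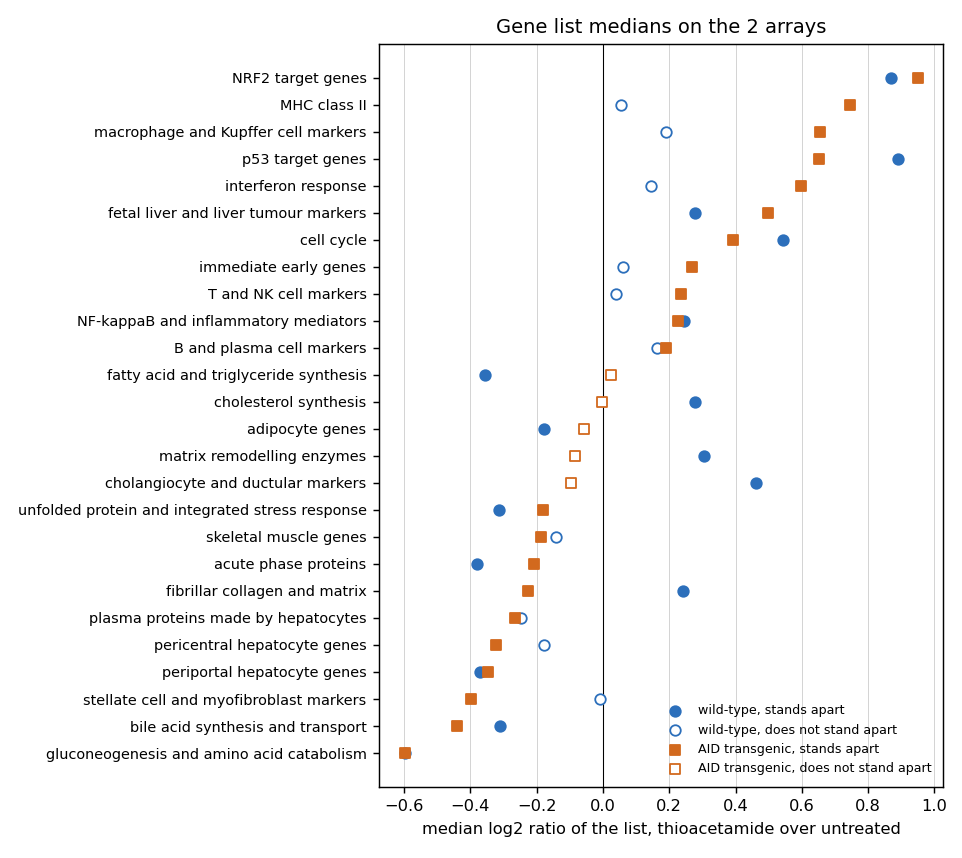
Median log2 ratio of treated over untreated liver (horizontal axis) of 26 gene lists on the wild-type array (blue circles) and the AID transgenic array (orange squares), filled where the list stood apart from matched random lists, with the 4 sex lists left out. Of these lists 10 stood apart the same way on both arrays, and 1, fibrillar collagen and matrix, in opposite ways; relative to all genes, median centring turned the sign of the median of 1 of 19 lists that stood apart on the wild-type and 7 of 23 on the AID transgenic array, sex lists included.

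The difference between the 2 treatment ratios asks where the response of the genotypes differed. In the AID transgenic liver the ratios of acute phase, MHC class II, macrophage and interferon genes were higher than in wild-type, and those of stellate, matrix, ductular, p53 and cell cycle genes were lower. The acute phase list had a median difference of 0.45 (percentile 100) over 29 genes, 4 at least 2-fold higher and 5 lower. Its leading members were Saa2 at 4.98 ± 0.44 and Saa1 at 3.93 ± 0.39, and Hamp2 at -3.28 ± 0.44, the metallothionein genes Mt2 and Mt1 at -2.32 ± 0.33 and -2.11 ± 0.32, Fgl1 at -1.44 and Hamp at -1.36 went the other way. As a list, acute phase genes differed between the untreated livers (median -0.34, percentile 0.0) and did not stand apart between the treated livers (median -0.02, percentile 42.05). MHC class II had 0.83 with 4 of 9 genes higher, macrophage markers 0.42 with 2 of 35 higher and 1 lower, and interferon response genes 0.39 with 1 of 38 higher, each at percentile 100. Of 23 stellate markers 6 were lower (median -0.46), of 29 collagen and matrix genes 7 were lower and 1, Col5a3 at 1.92 ± 0.32, higher (median -0.46), and of 22 ductular markers 6 were lower (median -0.38), each at percentile 0.0. Acta2 had -1.56 ± 0.36, Col1a1 -2.03 ± 0.34 and Krt19 -1.46 ± 0.37. Of 24 p53 targets 3 were lower (median -0.39, percentile 0.0), with Phlda3 at -1.23 ± 0.53. Of 36 cell cycle genes 2, Ccnd1 at -1.96 ± 0.41 and Mki67 at -1.01 ± 0.41, were lower (median -0.16, percentile 0.0), and the list lost its place with genes well above background in every channel (percentile 11.2). NRF2 targets (median -0.01, percentile 37.3) and gluconeogenesis genes (0.01, 54.4) did not stand apart.

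These differences came with the difference in sex-linked transcripts. The male-biased list had a median difference of 1.17 with 17 of 26 genes higher, and the female-biased list -1.60 with 22 of 31 lower. The highest named genes were Cyp4a12a at 6.39 ± 0.67, Saa2, Cyp4a12b at 4.95, Nat8f5 at 4.37, Cabyr at 4.18, Saa1, Cyp7b1 at 3.27, Moxd1 at 3.16, Il1b at 2.86 and Zfp982 at 2.80. The lowest were Cyp26b1 at -3.96 ± 0.44, Hamp2, Cyp2b10 at -3.24, the X-linked gene Xlr3b at -3.05, Cyp3a41b at -2.65, Prom1 at -2.48, Depp1 at -2.37, Nt5e at -2.32, Mt2 and Akr1c18 at -2.27. In all, 159 of 17104 genes had a difference of at least 1 and 180 of -1 or less. Of these, 93 and 100 were also 2-fold apart between the treated livers and 27 and 27 between the untreated livers. Without sex-list, X-linked and Y-linked genes the counts were 139 and 152.

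The untreated livers of the 2 genotypes differed least, with 44 of 14296 genes at least 2-fold higher in AID transgenic than in wild-type and 42 lower. The highest named genes were Tff3 at a log2 ratio of 3.15, the macrophage receptor gene Marco at 2.54, Ccl21a at 2.06, Enho at 1.78 and Rnu1b6 at 1.77. The lowest were Saa2 at -2.71, Saa1 at -2.28, Aatk at -2.21, Moxd1 at -1.69 and Pde5a at -1.67. Of 21 stellate markers 3 were higher, Acta2 at 1.41, Cnn1 at 1.34 and Myl9 at 1.06 (median 0.22, percentile 100), and the collagen and matrix list had a median of 0.24 (percentile 100) with 0 of 24 genes at 2-fold. Acute phase genes (median -0.34, 2 of 28 lower), fatty acid and triglyceride synthesis genes (-0.32, 3 of 30 lower) and PPAR alpha and fatty acid oxidation genes (-0.20, 1 of 37 lower) each lay at percentile 0.0. Cell cycle genes also stood apart below the random lists (median -0.13, percentile 0.02, 1 of 29 lower), under each of 9 alternatives. Ddx3y had 0.10 and the male-biased list -0.09 (percentile 1.75). The female-biased list stood apart with 3 of 20 lower (median -0.11, percentile 0.34), but not under 5 of its 8 alternatives.

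Between the treated livers, immune genes were higher and p53, cholesterol and ductular genes lower in AID transgenic than in wild-type mice. Of 9 MHC class II genes 4 were higher (median 0.90), led by H2-Ab1 at 1.59 and Cd74 at 1.48. Of 35 macrophage markers 5 were higher (median 0.51), led by Marco at 2.42 and Cd5l at 1.41, and 2, Gpnmb at -1.25 and Trem2 at -1.24, were lower. Marco was also higher between the untreated livers, at 2.54, and its treatment ratios differed by only -0.12 ± 0.30. Interferon response genes had a median of 0.38 with 0 of 38 at 2-fold. Of 24 p53 targets 4 were lower (median -0.30), led by Phlda3 at -1.73 and Tnfrsf10b at -1.29, and cholesterol synthesis genes had a median of -0.40 with 0 of 25 at 2-fold. Ductular markers had -0.27 with 2 of 22 lower, collagen and matrix genes -0.25 with Col1a1 at -1.16, and stellate markers -0.21 with 1 of 23, the retinol esterification gene Lrat, lower. Acta2 had -0.16. Percentiles were 100 for the immune lists and 0.0 for the others.

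Sex-biased genes led this comparison too. The highest named genes were Cyp4a12a at 5.23, Tff3 at 5.01, Cyp4a12b at 3.92, Serpina4-ps1 at 3.85 and Cyp7b1 at 3.38, and among the lowest were Cyp3a44 at -6.73, Cyp2b13 at -6.21, Cyp2b10 at -4.10 and Cyp26b1 at -3.59. The male-biased list had a median of 1.08 with 15 of 26 higher, and the female-biased list -1.71 with 23 of 31 lower. In all, 125 of 17076 genes were higher and 130 lower, 255 together, and 209 together without sex-list, X-linked and Y-linked genes. Cytochrome P450 and flavin monooxygenase genes, with 14 of 42 lower and 4 higher (median -0.15, percentile 0.0), did not stand apart without sex-biased members (median 0.02, percentile 71.6).

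Genes of the deaminase, base excision and mismatch repair list, which act on or after cytosine deamination, did not stand apart in any of the 5 comparisons. None of the 31 measured genes reached 2-fold in either treatment ratio or in their difference. The list medians were 0.11 in wild-type (percentile 89.7) and 0.11 in AID transgenic mice (percentile 93.2), and the difference had a median of -0.04 (percentile 22.8). Between the genotypes they were 0.00 in untreated (percentile 47.6) and -0.06 in treated livers (percentile 9.07).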

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

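The tests of Xist on the wild-type array, of the cell type lists and of sex on the AID transgenic array, and of sex between the treated livers were chosen only after the result was seen. The tests of the sex-biased lists and of the other probes of shared genes were set before their results were seen.

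Some genes had opposite directions at 2-fold on the 2 arrays, and the difference between genotypes was not tested, since each rests on 1 array. Saa2 had -2.48 ± 0.31 in wild-type and 2.504 ± 0.31 in AID transgenic mice, a difference of 4.98, and Saa1 -2.13 and 1.80, a difference of 3.93. In both, the untreated wild-type liver was above the untreated AID transgenic liver. Nat8f5 had -2.30 and 2.07 (difference 4.37) and Esm1, which the rule for named genes did not pick, -1.16 and 1.27 (difference 2.44). Xlr3b had 1.54 and -1.51 (difference -3.05) and Depp1 1.05 and -1.32 (difference -2.37). The collagen and matrix list stood apart above the random lists in wild-type and below them in AID transgenic mice, with a median difference of -0.46, also untested.

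Probes without a gene name, which enter no comparison, also passed 2-fold. On the wild-type array 41 were higher and 47 lower of 5101 measured, and on the AID transgenic array 26 were higher and 18 lower of 5148.

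Sex-linked transcripts differed between the channels of the wild-type array. A candidate explanation is that the treated wild-type RNA came from a female liver and the other 3 RNAs from male livers. On the wild-type minus AID transgenic difference the male-biased list had a median of -1.17 (percentile 0.0) and the female-biased list 1.60 (percentile 100), as that explanation needs. Loss of Y-linked transcripts in a male liver is argued against by Xist, well above background in the treated channel and at least 6.18-fold higher there (log2 ratio 2.67, with the untreated channel not well above background). Whether the animals differed in sex by design or 1 RNA was exchanged with an outside sample stays open, and no biological explanation was tested.

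The 2 treatment ratios shared genes at 2-fold, which dye bias of single probes might also give without a dye swap. For 48 genes picked by their brightest probe at 2-fold the same way on both arrays, the other 56 probes had a median log2 ratio of 0.82 in that direction (95% interval over genes 0.58 to 1.11), against 1.34 for the brightest probes. The other probes went the same way for 43 genes. The interval lies above 0.3, the limit set for dye bias alone, but reaches below the 0.6 set against it, so a part played by dye bias stays open, as does the biological explanation, thioacetamide.

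Macrophage and MHC class II markers were higher and stellate cell markers lower on the AID transgenic array. A lower share of hepatocytes that raised all other cell types alike would raise both lists. The stellate list median lay -1.05 from the macrophage list median (95% interval over members, which are not replicates, -1.36 to -0.71). This comparison uses the lists that define the pattern, so it cannot decide whether the share of hepatocytes differed. Livers of different sex in its 2 channels are argued against by Ddx3y at -0.11, within its scanner error of 0.20, with Xist not well above background in either. For the same markers between the treated livers, sex and genotype cannot be told apart, since the male-biased list had a median of 1.08 there. The contractile genes Acta2, Cnn1 and Myl9 were also higher in the untreated AID transgenic than in the untreated wild-type liver. Acta2 had 1.41 between the untreated livers and -0.155 between the treated livers. Its lower ratio than in wild-type thus lay mostly with the untreated livers. For the stellate list the medians were 0.22 and -0.21, so both pairs of livers contributed. Whether an untreated liver was unusual cannot be told with 1 array per genotype, and an effect of the transgene stays open, untested.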

How the results depend on the processing

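Of the lists that stood apart, 1 crossed to the other side of the random lists under an alternative, planned or added after seeing the data. P450 and flavin monooxygenase genes, which stood apart below, had a median of 0.12 (percentile 95.03) without shared members on the difference, and between the treated livers 0.042 without shared and 0.0205 without sex-biased members, none standing apart. Median centring, which raised the median of all genes, turned the sign of the median of 6 of 19 such lists in wild-type and 9 of 23 in AID transgenic mice, and relative to all genes of 1 and 7. The lists singled out below were chosen after seeing the data. Of 885 alternative values of gene lists that stood apart, 824 still stood apart the same way, though leaving out sex-biased members removed none in 72 of these and leaving out shared members none in 32, and of 525 values of named genes 401 moved by no more than the scanner error. Of 110 alternative gene counts 71 stayed within 1.5 times, among them those with no background correction, with the brightest probe, with the scanner's p under 0.01 and without sex-list, X-linked and Y-linked genes. Leaving out the filter on background removed no counted gene and so tested nothing for the counts. The others follow as higher and lower, and their cause was not tested except for 3-fold, a stricter threshold. The deposited values equal the scanner's log ratio, so they repeat its counts and are no separate check, although both are among the 110. For wild-type treatment, an offset of 0 gave 782 higher, median centring 1730 and 102, the scanner's signals and the deposited values both 1584 and 602, and 3-fold 98 and 94. For AID transgenic treatment these were 620 and 269, 1358 and 53, 1528 and 466, and 57 and 43. For the difference of the ratios an offset of 0 gave 376 and 504, the scanner's signals and the deposited values 816 and 918, and 3-fold 58 and 72. For untreated livers the offset gave 106 and 99, the scanner's signals 215 and 207 and 3-fold 13 and 8, and for treated livers 238 and 230, 461 and 444, and 46 and 50. The Pearson correlation was 0.743 with median centring. Shared higher genes were 268 with the offset, 815 with median centring, 749 with the scanner's signals and 31 at 3-fold, and shared lower genes 19 with median centring, 161 with the scanner's signals, 1.1e+02 (rounded) over single probes and 15 at 3-fold. The losses given here are not complete, and heat shock genes between untreated livers, for example, no longer stood apart under 6 of 9 alternatives. Among the lists singled out, cell cycle no longer stood apart on the difference with the scanner's signals (median -0.21) and with every channel well above background (-0.064). Bile acid genes in wild-type did not with median centring (0.37), the brightest probe (-0.17) or without shared or sex-biased members (-0.23 in each). Pericentral genes did not on the AID transgenic array without shared members (-0.15), and on the difference with the offset (-0.15), the scanner's signals (-0.15) and without shared members (-0.10). The pericentral list has no sex-biased members, and its percentile on the difference (median -0.15, 0.36 and in a second draw of random lists 0.53) lies too close to the threshold to hold. Periportal genes in wild-type did not without shared members (-0.27), nor female-biased genes on the AID transgenic array with median centring (0.30) and with every channel well above background (0.13). Signal over background limited the values in Cy3 most, where 56% and 53.9% of spots were well above it. No paired analysis was possible because there is 1 array per genotype, though each treatment ratio is already taken within its array.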

Other observations

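Lipid genes and stress genes formed further groups. Of 31 fatty acid and triglyceride synthesis genes 6 were lower and 1 higher in the treated wild-type liver (median -0.36, percentile 0.0, with median centring 0.13), with Elovl3, a male-biased gene, at -4.27 ± 0.48, the lipogenic regulator Thrsp at -1.99 ± 0.27, Lpin1 at -1.92 ± 0.32 and the fatty acid transporter gene Cd36 at 2.15 ± 0.29. The same list did not stand apart on the AID transgenic array (median 0.02, percentile 51.9). Cholesterol synthesis genes stood apart in wild-type (median 0.28, percentile 99.89), with 2 of 25 higher, Sqle at 1.92 ± 0.27 and Hmgcs1 at 1.42 ± 0.24, but not with median centring (percentile 98.6), and had a median of 0.00 in AID transgenic mice. PPAR alpha and fatty acid oxidation genes stood apart on neither array (percentiles 23.7 and 15.2), although 8 of 37 were higher in wild-type. Genes of the unfolded protein and integrated stress response were lower in both genotypes (medians -0.31 and -0.18, percentiles 0.0 and 0.1), with 6 and 3 of 29 at 2-fold. They did not stand apart with median centring (medians 0.33 and 0.38, percentiles 1.91 and 2.15), where the AID transgenic median lay 0.04 above all genes, and in AID transgenic mice not with the scanner's signals either (percentile 2.24). Asparagine synthetase, Asns, had -1.92 ± 0.38 in wild-type, where Vldlr and Trib3 were higher at 1.76 ± 0.46 and 1.38 ± 0.24, and Chac1 had -1.88 ± 0.30 in AID transgenic mice. Plasma protein genes of hepatocytes stood apart on the AID transgenic array (median -0.27, percentile 0.04, but 0.16 above all genes with median centring, and not apart with the brightest probe, percentile 1.15), with the apolipoprotein gene Apoa1 at -1.84 ± 0.27 and Mbl2 at 1.08 ± 0.22, and lay at percentile 0.65 in wild-type (median -0.25). Acute phase genes stood apart on the AID transgenic array with 4 of 29 higher and 4 lower (median -0.21, percentile 0.11, equal to all genes within 0.003 with median centring). P450 and flavin monooxygenase genes went both ways in wild-type, 9 higher and 6 lower of 42, with a median of -0.17, a mean of 0.15 and a percentile of 1.12, and lay at percentile 0.62 in AID transgenic mice.

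Other cell types and tissues gave smaller values. T and NK cell markers stood apart on the AID transgenic array (median 0.24, percentile 100, but with median centring 0.13 below all genes and not apart, percentile 97.33), led by Ccl5 at 1.70, as did B and plasma cell markers (0.19, percentile 99.9, but 0.01 below all genes with median centring, and not apart with every channel well above background, percentile 96.47), led by Ly6d. In wild-type they lay at percentiles 52.0 and 98.7. Inflammatory mediators stood apart in wild-type too (median 0.25, percentile 99.95, but 99.44 with no filter on background), with Tnfrsf12a at 1.30 and Ccl2 at 1.06. Liver endothelial markers (percentiles 0.77 and 5.95), neutrophil markers (8.65 and 36.4) and erythroid genes (51.3 and 10.96) stood apart on neither array. Of the markers of neighbouring tissues, pancreatic acinar genes lay at percentiles 1.60 and 4.13, skeletal muscle genes at 0.83 and 0.42 and adipocyte genes at 0.45 and 14.7. The muscle list (AID transgenic median -0.19) and the adipocyte list (wild-type median -0.18) each lost their place under most alternatives. Circadian clock output genes stood apart on neither array (percentiles 4.01 and 13.4). Arntl had 2.62 in wild-type and 1.62 in AID transgenic mice, and Lpin1 of the same list had -1.92 and -2.44. A list median can miss members that move in opposite ways, so a difference in time of day was not tested. The list was lower in AID transgenic than wild-type untreated livers (median -0.23, percentile 0.0). Between the treated livers it stood apart as well, under each of 9 alternatives. Immediate early genes stood apart on the AID transgenic array (median 0.27, percentile 100), with the nuclear receptor gene Nr4a1 at 2.56 ± 0.33. Heat shock genes (percentiles 75.6 and 0.67) and housekeeping genes (72.6 and 97.6) stood apart on neither. Heat shock genes and liver endothelial markers did stand apart on the difference of the ratios and between the treated livers, under each of 9 alternatives.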
